A study of Homo sapiens with 14 samples.

How the data were processed

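Guide counts were analysed for 14 libraries of a pooled CRISPR interference screen in HEK293 FLP-In cells. Per the labels' protocols, cells expressing the DOR-APEX2 fusion and dCas9-KRAB were transduced at a multiplicity of about 0.2 with the hCRISPRi-v2-top5 library. Puromycin at 0.75 µg/ml was applied for 3 days, from 2 days after transduction. The cells were stimulated, reacted for 1 minute with 100 µM Amplex UltraRed and 50 µM hydrogen peroxide, and sorted into quartiles by fluorescence. Guides were amplified from genomic DNA in 27 cycles and sequenced. The values are counts per guide, deposited by the authors as whole numbers with no normalization, and each table lists a guide name and a count. The submitters' processing notes name Bowtie, with no version; the genome build behind the positions in the guide names and the other counting settings are not given in the sources used here. Guides without a read are not listed, and were taken as 0 when the partner library of the sublibrary listed them.

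Samples were grouped by the titles in the labels into sublibrary and quartile, 1 library per group. The H4 top table ended within a guide's name after 35 complete guides with 70718 counts in all and 0 non-targeting guides, so H4 was left out of the comparisons and its bottom library was used for abundance only. The 6 compared sublibraries held 91463 guides. PCR reads without molecular identifiers are not independent molecules, so spreads expected from counting cover counting error only. The intervals given describe sampling over genes and hold no spread between sorts.

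Each count was raised by a pseudocount of 1 and divided by the library total, and log2(top/bottom) was centred on the median of the non-targeting guides of the same sublibrary. The median of all guides lay between -0.00 and 0.02 of that centre. A guide entered with at least 50 counts in either library, which left 91088 and removed 375. A target, the guides that share a gene symbol and a start label, entered with at least 3 guides: 17071 targets had 5, 975 had 4 and 70 had 3. Each target's mean was set against 100000 random draws of as many guides from its own guides and the sublibrary's non-targeting guides, 241 to 308 of them, in a two-sided permutation test. The smallest p the draws could give was 1e-05, reached by 265 targets, and Benjamini-Hochberg adjustment over all 18116 targets made it 6.84e-04. The threshold was an adjusted p of 0.05. edgeR's quasi-likelihood test could not be the main test, since 1 library per group leaves no residual degrees of freedom for a guide. It was run as an alternative on the 17071 targets with 5 guides, with each guide as a block and library sizes scaled on non-targeting guides. Guides at 360 positions were listed under more than 1 target; 6 called targets share guides with another.

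The comparisons, the 32 gene lists, the rule for named genes and the alternatives not named as added were fixed before the data were examined. Named genes were DNAJC13 and OPRD1; the 12 highest and 12 lowest primary-start targets by mean over the SD of non-targeting guides, among those past the threshold with at least 4 guides and 80% of guides on the side of the mean; the first 2 per direction in each sublibrary by the same ranking; and in each list the up to 4 members farthest from 0. Some genes that these rules take, and 2 of the lists, are not reported here. Other members that passed are given because a whole count is listed. VPS35, VPS26A, the neighbours of named genes and the second start of SLC1A5 were chosen after their values were seen. A gene with several starts was taken at its primary start. Each list's median was ranked among 10000 random lists of the same size, matched on sublibrary and mean guide count, as a description of these libraries. Guide abundance was the log2 of the summed counts relative to the non-targeting median.

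The test was checked on simulated counts for the comparison of top against bottom over all sublibraries. Of 18115 simulated targets, 100 of 100 changed by 1.0 on the log2 scale and 67 of 100 changed by 0.5 were called, with 2 calls among 17915 unchanged targets. edgeR, on 17010 targets, called 96 of 96, 70 of 95 and 14 of 16819. The simulated guides had normally distributed noise of one SD per sublibrary, without outlying guides. In the real H7 libraries the farthest non-targeting guide lay 1.82 from 0, with an SD of 0.333. The simulated rates therefore may not hold for the real data.

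Neighbouring targets were sought by matching gene symbols and older symbols to a RefSeq gene table of assembly GRCh38.p14, used for names and chromosomes only; 18814 of 18905 symbols matched. Of the called targets 19.0% had guides within 1000 bases of guides for another gene, against 12.0% of all targets, and repression there can reach both genes. In 20 called targets that neighbour was called in the same direction, and in 0 in the opposite. Targets that share guides with another gene were not left out of this count. Their direction is at least partly fixed in advance. Among the called named genes, ATP6V1A, MPHOSPH10, NFS1, RBM12, RPS18 and TCP1 have a neighbour within this distance in H4, which was not compared.

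Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.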

Results

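The screen asked which human genes, when repressed, change how much delta opioid receptor (DOR) remains after an agonist has acted. HEK293 FLP-In cells, a human embryonic kidney line with a single docking site for transgenes, expressed DOR fused to the peroxidase APEX2, together with the repressor dCas9-KRAB. The cells received guide RNAs from a genome-wide CRISPR interference library with 5 guides per gene start, split into 7 sublibraries named H1 to H7. After 8 days the cells were stimulated for 90 minutes with 10 µM DADLE, an opioid peptide agonist. Intact cells were then reacted with Amplex UltraRed, which peroxidases turn into a fluorescent product. The brightest and the dimmest quartile of each sublibrary were sorted, and the guides in their genomic DNA were sequenced.

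There were 14 libraries in 14 groups, 1 bottom and 1 top library per sublibrary, so no sort was repeated and the differences have no replicate check. Every library came from cells stimulated with DADLE, and none from unstimulated cells. A ratio therefore cannot tell a change in receptor loss after the agonist from other changes in the APEX2 signal. The 12 libraries of H1, H2, H3, H5, H6 and H7 were compared. Their total guide counts ran from 18054418 in H6 bottom to 34636612 in H2 top, with a median count per listed guide from 1193 to 2004. The H4 top table held 35 complete guides, and H4 was not compared. A gene's value is the mean over its guides of log2(top/bottom), centred on the non-targeting guides of its sublibrary, with the SD over guides. Positive values mean that cells carrying the guides were more frequent in the bright quartile. The p-values come from a two-sided permutation test of a gene's guides against non-targeting guides with Benjamini-Hochberg adjustment. They compare the libraries of one sort, not repeated sorts, and the smallest adjusted value that the draws could give was 6.84e-04.

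Guides against subunits of the proton pump of lysosomes, the endosome-to-lysosome tethering machinery, the proteasome and the chaperonin were enriched in bright cells. Guides against ALAD of heme synthesis, ribosomal proteins and ribosome assembly factors were enriched in dim cells. Of 18116 targets (gene starts) of 16684 genes, 701 passed the threshold, or 3.87%. Of these, 427 were higher in the top quartile, with a median log2 ratio of 0.62, and 274 were higher in the bottom quartile, with a median of -0.53. All guides of a target lay on one side of 0 for 66.9% of the called targets and for 8.51% of the others. The calls rest on the means of these same guides, so the difference is not a separate check. Leaving out the guide farthest from 0 in every target lowered the count to 310, and edgeR's quasi-likelihood test with guides as blocks called 243.

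Calls were unevenly spread over the sublibraries. H3 had 136 targets higher in the top and 108 higher in the bottom library, H2 had 124 and 67, H5 had 90 and 59, and H1 had 45 and 19. H6 had 20 and 11, and H7 had 12 and 10. The SD of the non-targeting guides was 0.215 in H3 and 0.333 in H7, against 0.057 and 0.085 expected from counting alone. Read counting thus did not account for most of this spread, and the number of cells per guide is not known from the counts. In the other 4 compared sublibraries it lay between 0.229 and 0.272.

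**Figure D1:**
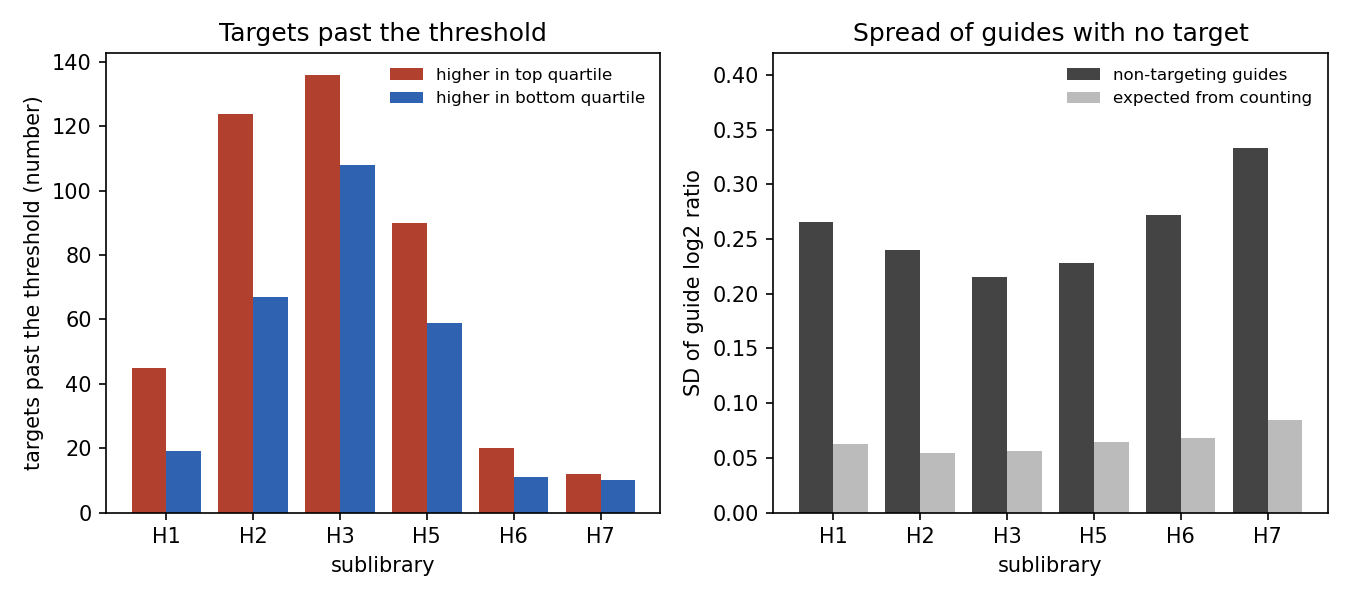
The left panel plots the number of targets past the threshold per sublibrary, higher in the top (red) or bottom (blue) quartile; the right panel plots the SD of guide log2 ratios of non-targeting guides (dark) beside the SD expected from counting alone (light). H3, with the smallest SD of 0.215, had 136 and 108 such targets, and H7, with the largest of 0.333, had 12 and 10.

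DNAJC13, the endosomal J-domain protein named in the title of the series, was enriched in bright cells. Its mean log2 ratio was 0.73 ± 0.25 (SD, n = 5 guides), a 1.66-fold higher share in the top than in the bottom library, with a permutation adjusted p of 6.84e-04. All 5 guides lay above 0, from 0.47 to 1.08, with 1245 to 1919 counts in the bottom and 2337 to 3586 in the top library. The guides carry positions 132136381 to 132136592 in their names, in a genome build that is not given in the sources used here. Under the 16 alternative settings the value stayed between 0.65 and 0.88, and DNAJC13 passed the threshold in each. OPRD1, the cell's own gene for DOR, had a mean of 0.16 ± 0.17 (SD, n = 5 guides) and did not pass, with a permutation adjusted p of 0.656. Whether these guides also repress the DOR-APEX2 fusion, which gave the signal, is not known from the counts.

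Guides against ALAD, an enzyme in the synthesis of heme, the cofactor of APEX2, were enriched in dim cells at -0.96 ± 0.29. FECH of the same pathway had -0.86 ± 1.19 and the mitochondrial transporter ABCB10 went the other way at 0.60 ± 0.98 (SD, n = 5 guides each), both with 3 of 5 guides on the side of their mean. Of 16 alternatives in the choice of guides, scaling and test, FECH passed in 13 and ABCB10 in 12; both calls ended by rank sum, without the farthest guide and with edgeR.

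The genes far toward the dim side by size over non-targeting spread included a transporter and several RNA and ribosome factors. SLC1A5, a neutral amino acid transporter, had -2.63 ± 0.32 at its first and -0.50 ± 0.18 at its second start. RIOK2, a kinase of small ribosomal subunit maturation, had -1.74 ± 0.53, and the ribosomal RNA processing factors NOL6, RRP9 and MPHOSPH10 had -1.36 ± 0.96, -1.23 ± 0.77 and -1.21 ± 0.76. CBLL1, a subunit of the m6A RNA methyltransferase, had -1.39 ± 0.41 and YTHDC1, the nuclear reader of that mark, -1.20 ± 0.37. The mRNA export helicase DDX39B had -1.44 ± 0.28, superoxide dismutase SOD1 -1.40 ± 0.95 and the transcription factor MAFG -1.19 ± 0.51 (SD, n = 5 guides in each). Each had a permutation adjusted p of 6.84e-04; the call of NOL6 ended with edgeR and that of SOD1 by rank sum.

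Among the 12 genes farthest toward the bright side were ATP6V1A and ATP6V1B2 of the lysosomal proton pump at 2.87 ± 1.36 and 2.56 ± 0.76, and VPS16, a core of the HOPS tether, at 2.11 ± 0.51. The nucleoporin NUPL1 had 2.44 ± 1.00, the DNA polymerase delta subunit POLD2 2.11 ± 0.38 and the primase subunit PRIM1 1.95 ± 0.14. CCT4 of the chaperonin had 1.82 ± 0.13, the ubiquitin-like modifier NEDD8 1.76 ± 1.09, the proteasome subunit PSMD4 1.74 ± 0.52 and CNOT1, the scaffold of the CCR4-NOT deadenylase, 1.71 ± 0.84 (SD, n = 5 guides in each). These 10 had a permutation adjusted p of 6.84e-04. LSM6 and ZMYM5, at 2.41 ± 2.67 and 2.32 ± 3.97, each owed much of the mean to 1 guide with no count in the bottom library, whose log2 ratio depends on the pseudocount of 1. Without that guide the means were 1.22 and 0.58. The call of LSM6 ended with edgeR, that of NEDD8 by rank sum and that of ZMYM5 under 5 settings, the removal of guides listed in 1 library among them. NEDD8 guides lie among those of the overlapping readthrough gene NEDD8-MDP1, which had 1.54 in H1.

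**Figure D2:**
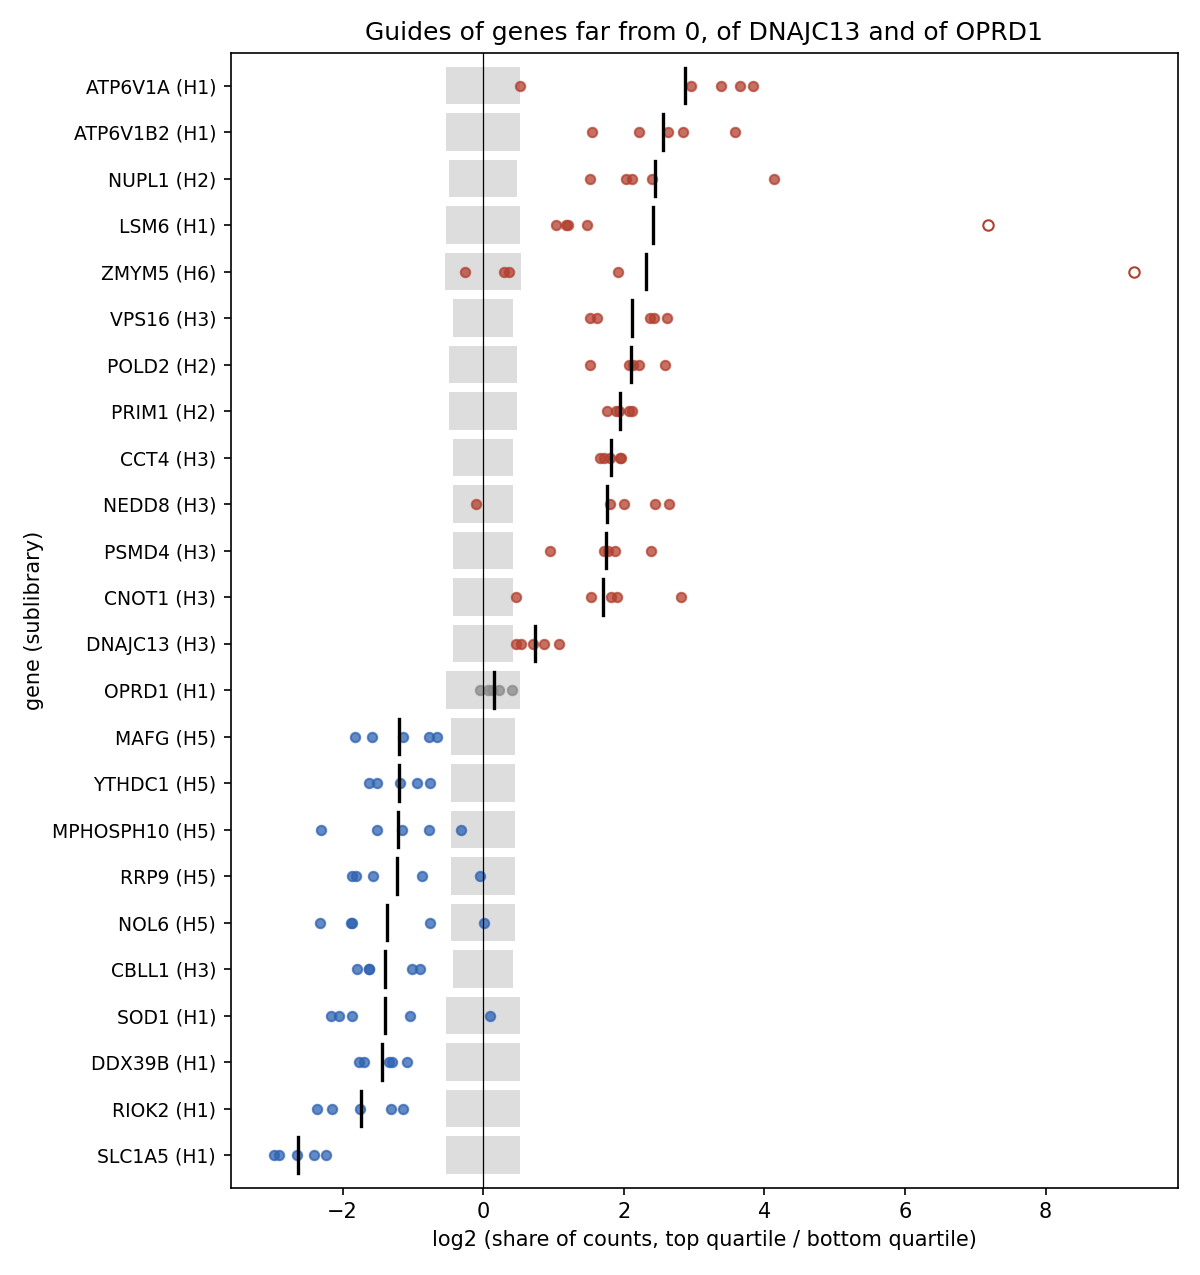
Each point is 1 guide, placed by its log2 ratio of the top to the bottom quartile; black bars are means over guides, grey boxes span 2 SD of the sublibrary's non-targeting guides on each side of 0, open points are guides with no count in 1 library, and colours show genes past the threshold toward the top (red) or bottom (blue) or not past it (grey). The 5 DNAJC13 guides sit between 0.47 and 1.08, above the box, whereas the OPRD1 guides lie inside it.

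Within each sublibrary the first 2 genes in each direction added the following. In H5, RBM12, an RNA-binding protein, had 1.76 ± 0.47 and RQCD1, a CCR4-NOT subunit, 1.72 ± 1.48. In H6, SLC12A9 had 1.02 ± 0.37, B3GNT2, which extends poly-N-acetyllactosamine chains, -0.59 ± 0.13 and SLC35G1 -0.58 ± 0.79. In H7, FAM101A had 0.89 ± 0.67, SRFBP1 -0.96 ± 0.33 and CTNNBL1 -1.06 ± 1.07, while C2orf54 at 2.45 ± 4.61 rested on 1 guide with no count in the bottom library. The mRNA 3' end processing factors FIP1L1 in H2 and SYMPK in H3 had -1.25 ± 0.16 and -1.07 ± 0.41 (SD, n = 5 guides in each). RBM12 guides lie among those of CPNE1, which is in H4. With no filter on guide counts the calls of SLC12A9, B3GNT2, SLC35G1, FAM101A, SRFBP1 and CTNNBL1 ended, and with edgeR those of RQCD1, SLC35G1, FAM101A, CTNNBL1 and C2orf54. Of 16 alternatives SLC12A9 and RQCD1 passed in 15, B3GNT2 in 14 and SLC35G1 in 10; of 15 that could be run, SRFBP1 passed in 14, FAM101A in 12, CTNNBL1 in 10 and C2orf54 in 9.

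Of 21 subunits and assembly factors of the V-ATPase, the proton pump of lysosomes, 10 were higher in the top library and 0 in the bottom; adjusted over the list alone, 11 and 0. The median was 0.36, at percentile 100 of matched lists. Beside ATP6V1A and ATP6V1B2, ATP6V1C1 had 1.68 ± 0.44 and the accessory subunit ATP6AP1 1.56 ± 0.62 (SD, n = 5 guides each). Of 24 members of the RAB5, RAB7, HOPS and CORVET list, which tether and fuse endosomes, 11 were higher in the top and 0 in the bottom; adjusted over the list alone, 13 and 1. The median was 0.30, at percentile 100. They included all of the compared HOPS subunits VPS11 (0.80), VPS16, VPS18 (0.55), VPS33A (0.40), VPS39 (1.01 ± 0.42) and VPS41 at its first start (1.19 ± 0.81), as well as RAB7A (1.00 ± 1.09). The guides of RABGEF1 (0.42) are also listed for KCTD7, and the call of RAB7A ended by the median, without the farthest guide and with edgeR.

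ESCRT genes sort ubiquitinated cargo into multivesicular bodies. Of 26 members, 3 were higher in the top library: HGS at 1.15 ± 1.39 with 3 of 5 guides on the side of its mean, CHMP6 at 1.08 ± 0.43 and UBAP1 at 0.61 ± 0.70; 0 were higher in the bottom. Adjusted over the list alone the counts were 7 and 0, with the median of 0.10 at percentile 99.9. The deubiquitinase USP8 had 0.30 ± 0.35 and did not pass. In the list of retromer, WASH and retriever, which recycle cargo from endosomes, DNAJC13 and VPS29 (0.72 ± 0.57) were higher in the top and COMMD1 (-0.34 ± 0.20) in the bottom, of 26 members. The list's median was -0.10, at percentile 0.020, and adjusted over the list alone 3 were higher in the top and 5 in the bottom. COMMD6 had -0.47 ± 0.21, and the retromer subunits VPS35 and VPS26A had -0.10 and -0.02; these did not pass. VPS29 guides lie among those of RAD9B, which had 0.11 and did not pass. By rank sum and with edgeR the calls of HGS, UBAP1, VPS29 and COMMD1 ended, and those of CHMP6 and DNAJC13 did not. Of 16 alternatives HGS and UBAP1 passed in 13, VPS29 in 14 and COMMD1 in 11.

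Of the 29 compared genes for lysosomal hydrolases and their sorting, 0 passed, also when adjusted over the list alone; the median was 0.02, at percentile 63.4, and the farthest, CTSL, NPC2, SCARB2 and SORT1, had 0.37, 0.15, 0.14 and 0.14. Of 13 endosomal phosphoinositide kinases and partners 0 passed by either adjustment; the median was -0.05 at percentile 11.1, with FIG4 at -0.26, MTM1 at -0.13, PIK3C3 at -0.11 and ATG14 at -0.07. Of 13 recycling and exocyst genes, RAB10 and EXOC3, both at 0.33, were higher in the top and 3 when adjusted over the list alone; the median was 0.02, at percentile 58.0. EXOC7 and EXOC8 had 0.28 and 0.21 and did not pass, and the calls of RAB10 and EXOC3 ended by rank sum, without the farthest guide and with edgeR; they passed in 11 and 13 of 16 alternatives.

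Of the receptor kinases, GRK6 was higher in the top library at 0.52 ± 0.19 (SD, n = 5 guides; permutation adjusted p 0.0338). GRK4, ADRBK2 and GRK5 had 0.13, 0.10 and 0.04 and did not pass. In this list of 5 the median was 0.10, at percentile 92.6, with 1 called also when adjusted over the list alone; both arrestins are in H4. Of 22 G protein and adenylyl cyclase genes only PDCL, a cochaperone of G protein beta subunits, passed, at 0.79 ± 0.25, by either adjustment; RGS4, ADCY9 and ADCY6 had 0.21, 0.19 and -0.22, and the median was 0.03 at percentile 67.6. Of 14 compared clathrin and AP2 genes, dynamin 2 (DNM2), which cuts coated pits from the membrane, was higher in the top library at 0.63 ± 0.48, the 1 call by either adjustment. SH3GL1, ITSN1 and PICALM had 0.23, 0.21 and -0.16, and the median was 0.08 at percentile 95.6. The clathrin chains and all 5 AP2 subunits are in H4. The call of GRK6 ended without the farthest guide, with the 3 farthest guides and when adjusted within sublibraries, and that of DNM2 by the median and with edgeR.

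Proteasome genes had the highest list median, 0.51, at percentile 100. Of 31 subunits, 18 were higher in the top library and 0 in the bottom; adjusted over the list alone, 23 and 0. Beside PSMD4, PSMB2 had 1.55 ± 0.49, PSMA5 1.38 ± 0.36 and PSMA1 1.21 ± 0.79 (SD, n = 5 guides each). Among 26 ubiquitin ligases of the NEDD4 family and the cullins with the NEDD8 system, 7 were higher in the top and 0 in the bottom, and 8 and 0 when adjusted over the list alone. They were NEDD8, its activating enzyme subunit UBA3 (1.07 ± 1.07), the ubiquitin-activating enzyme UBA1 (0.61), the cullins CUL2 (0.71 ± 0.64) and CUL4B (0.43), RBX1 (0.94 ± 1.33) and COPS6 (0.51). None of them is a NEDD4-family ligase. The median was 0.12, at percentile 99.96. ER folding and ER-associated degradation had 5 of 36 higher in the top, VCP (1.07 ± 1.08), SYVN1 (0.62 ± 0.36), HSPA5 (0.46 ± 0.61), HYOU1 (0.41 ± 0.35) and SEL1L (0.40), and 0 in the bottom; adjusted over the list alone, 8 and 2. Its median was 0.12, at percentile 99.99. RBX1 and VCP had 3 of 5 guides on the side of their mean. Of 16 alternatives PSMA1 and UBA3 passed in 15, CUL2 and VCP in 14, HYOU1 in 13, RBX1 in 12 and HSPA5 in 11, and edgeR ended each of these calls.

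The cytosolic chaperones parted. All 8 chaperonin subunits were higher in the top library, with CCT4, CCT3 at 1.78 ± 1.06, and TCP1 and CCT6A at 1.38 ± 0.45 and 1.38 ± 0.30. HSP90AA1 (-0.31), HSPA8 (-0.52), HSPA4 (-0.48) and STIP1 (-0.34) were higher in the bottom library. Of 28 members 8 and 4 passed, 11 and 4 when adjusted over the list alone, and the median of 0.06 was at percentile 94.8.

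Ribosomal protein genes moved toward the dim side. Of 77 members, 28 were higher in the bottom library and 0 in the top; adjusted over the list alone, 40 and 2. The median was -0.22, at percentile 0. Those farthest from 0 encode the small subunit: RPS24 had -0.92 ± 0.61, RPS28 -0.87 ± 0.24, RPS27A -0.87 ± 0.25 and RPS18 -0.86 ± 0.31 (SD, n = 5 guides each). RPS27A also encodes ubiquitin. The call of RPS24 ended with edgeR.

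Among transcription and mRNA genes, decay factors and Mediator subunits were found mostly on the bright side. Of 26 mRNA processing and decay factors 5 were higher in the top library, CNOT1, YTHDF2 (0.69 ± 0.53), PAN2 (0.57 ± 0.23), CNOT3 (0.45 ± 0.63) and CNOT8 (0.36); 0 were higher in the bottom. Adjusted over the list alone these were 8 and 1, with the median of 0.12 at percentile 99.9. Of 32 Mediator subunits 6 were higher in the top, led by MED23 at 1.17 ± 0.35, MED11 at 0.50 ± 0.41 and MED30 at 0.45 ± 0.19, whereas CCNC, cyclin C of its kinase module, had -0.68 ± 0.56. Adjusted over the list alone 8 and 2 passed, and the median was 0.13 at percentile 99.99. RNA polymerase II had POLR2H at 0.53 ± 0.53 and POLR2E at -0.43 ± 0.24 among 17, and 1 and 3 when adjusted over the list alone; SUPT5H and POLR2B had -0.33 and -0.28 and did not pass over all targets. Its median of -0.00 lay at percentile 30.1. Of 24 chromatin silencing genes EZH2 (0.38 ± 0.34) was higher in the top and SETDB1 (-0.42 ± 0.17) and ZNF638 (-0.39 ± 0.27) in the bottom, 1 and 2 also when adjusted over the list alone; ATF7IP had -0.26 and did not pass, and the median was -0.03 at percentile 7.66. Of 16 alternatives MED11, CCNC and POLR2E passed in 14, POLR2H and EZH2 in 13, MED30 and ZNF638 in 12 and CNOT3 in 11, and YTHDF2 in 11 of 15, and edgeR ended each of these calls. SETDB1 passed in 13 of 16, not without the farthest guide, by the median or with the 3 farthest guides.

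In the secretory pathway the results went both ways. Of 20 compared genes for ER insertion and signal peptides, the translocon subunits SEC61A1 at its first start (-0.88 ± 0.31) and SEC61B (-0.52 ± 0.24) and the signal peptidase subunit SPCS3 (-0.34) were higher in the bottom library. SEC63 (0.44 ± 0.21), SSR4 (0.42 ± 0.28) and SRP19 (0.37) were higher in the top. Adjusted over the list alone 4 and 4 passed, and the median of -0.05 was at percentile 2.41. N-glycosylation had 0 of 24 called over all targets and 1 higher in the top when adjusted over the list alone; RPN1, STT3A, DHDDS and DDOST had 0.53, -0.27, 0.25 and 0.22, and the median of 0.00 was at percentile 36.8. Of 27 compared COPII, COPI, TRAPP and COG genes ARCN1 (0.48 ± 0.38) was higher in the top and COG3 (-0.34 ± 0.19) in the bottom, 1 and 1 by either adjustment; ARF4 and TRAPPC3 had 0.36 and 0.35 and did not pass, and the median was 0.05 at percentile 94.96. Without the farthest guide and with edgeR the calls of SEC63, SSR4, ARCN1 and COG3 ended, and that of COG3 also by the median and with the 3 farthest guides.

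Nutrient signalling and sterol genes were also mixed. Of 30 genes of mTORC1 and nutrient sensing, LAMTOR5 (-0.75 ± 0.24), FLCN (-0.54 ± 0.20) and LAMTOR3 (-0.51 ± 0.25) were higher in the bottom library, whereas DEPDC5, a negative regulator of mTORC1, had 0.63 ± 0.50. Adjusted over the list alone 2 were higher in the top and 6 in the bottom, and the median of -0.04 was at percentile 2.24. Of 23 cholesterol synthesis genes CYP51A1 (0.77 ± 0.27) and SREBF2 (0.41 ± 0.40) were higher in the top and PMVK (-0.48 ± 0.27) in the bottom, 2 and 3 when adjusted over the list alone; DHCR7 had -0.44 and did not pass over all targets, and the median was -0.04 at percentile 5.38. Without the farthest guide the calls of LAMTOR3, DEPDC5, SREBF2 and PMVK ended; of 16 alternatives they passed in 14, 13, 13 and 12.

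Of 24 peroxide and thiol genes, heme oxygenase HMOX1 (1.04 ± 0.44) and the glutathione peroxidase GPX1 (1.02 ± 0.90) were higher in the top library, and SOD1 and KEAP1 (-0.39 ± 0.25) in the bottom; adjusted over the list alone, 3 and 3. The median was 0.00, at percentile 46.3. Of 15 iron uptake and iron-sulfur cluster genes NFS1 (1.10 ± 0.92) and the mitochondrial iron importer SLC25A28 (0.44 ± 0.26) were higher in the top and 3 when adjusted over the list alone; MMS19 and IREB2 had 0.33 and 0.24, and the median was 0.02 at percentile 58.6. The pentose phosphate pathway had 0 of 9 called by either adjustment, with a median of 0.03 at percentile 67.4 and PGD, RPIA, IDH1 and TALDO1 at 0.16, -0.08, 0.07 and 0.07. With edgeR the calls of GPX1, KEAP1, NFS1 and SLC25A28 ended; of 16 alternatives they passed in 14, 13, 15 and 14. Of 13 ABC efflux pumps and aquaporins 0 were called by either adjustment; the median of 0.01, against a mean of -0.01, was at percentile 49.6, and ABCC4, ABCC3, AQP3 and AQP9 had 0.12, 0.12, -0.18 and -0.17.

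Of 32 respiratory complex I genes, NDUFB2 passed at 0.37 ± 0.30, the 1 call by either adjustment, yet 26 means were above 0 and the median of 0.11 was at percentile 99.99; NDUFA9, NDUFB10 and NDUFB6 had 0.43, 0.43 and 0.25. Of 23 actin and microtubule motor genes 6 were higher in the top library, and 9 when adjusted over the list alone, with 0 in the bottom. They were the capping protein CAPZB (1.20 ± 1.26), cofilin CFL1 (1.09, with 4 of 5 guides above 0), ACTR2 (0.98 ± 1.06), ARPC2 at its first start (0.60 ± 0.99), ARPC3 (0.58) and ARPC1A (0.35), the last 4 from the actin-nucleating Arp2/3 complex. The median was 0.10, at percentile 99.6. Of 16 alternatives NDUFB2 passed in 11, CAPZB in 15, CFL1 in 12, ACTR2 in 13 and ARPC2 in 8, and edgeR ended each of these calls.

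**Figure D3:**
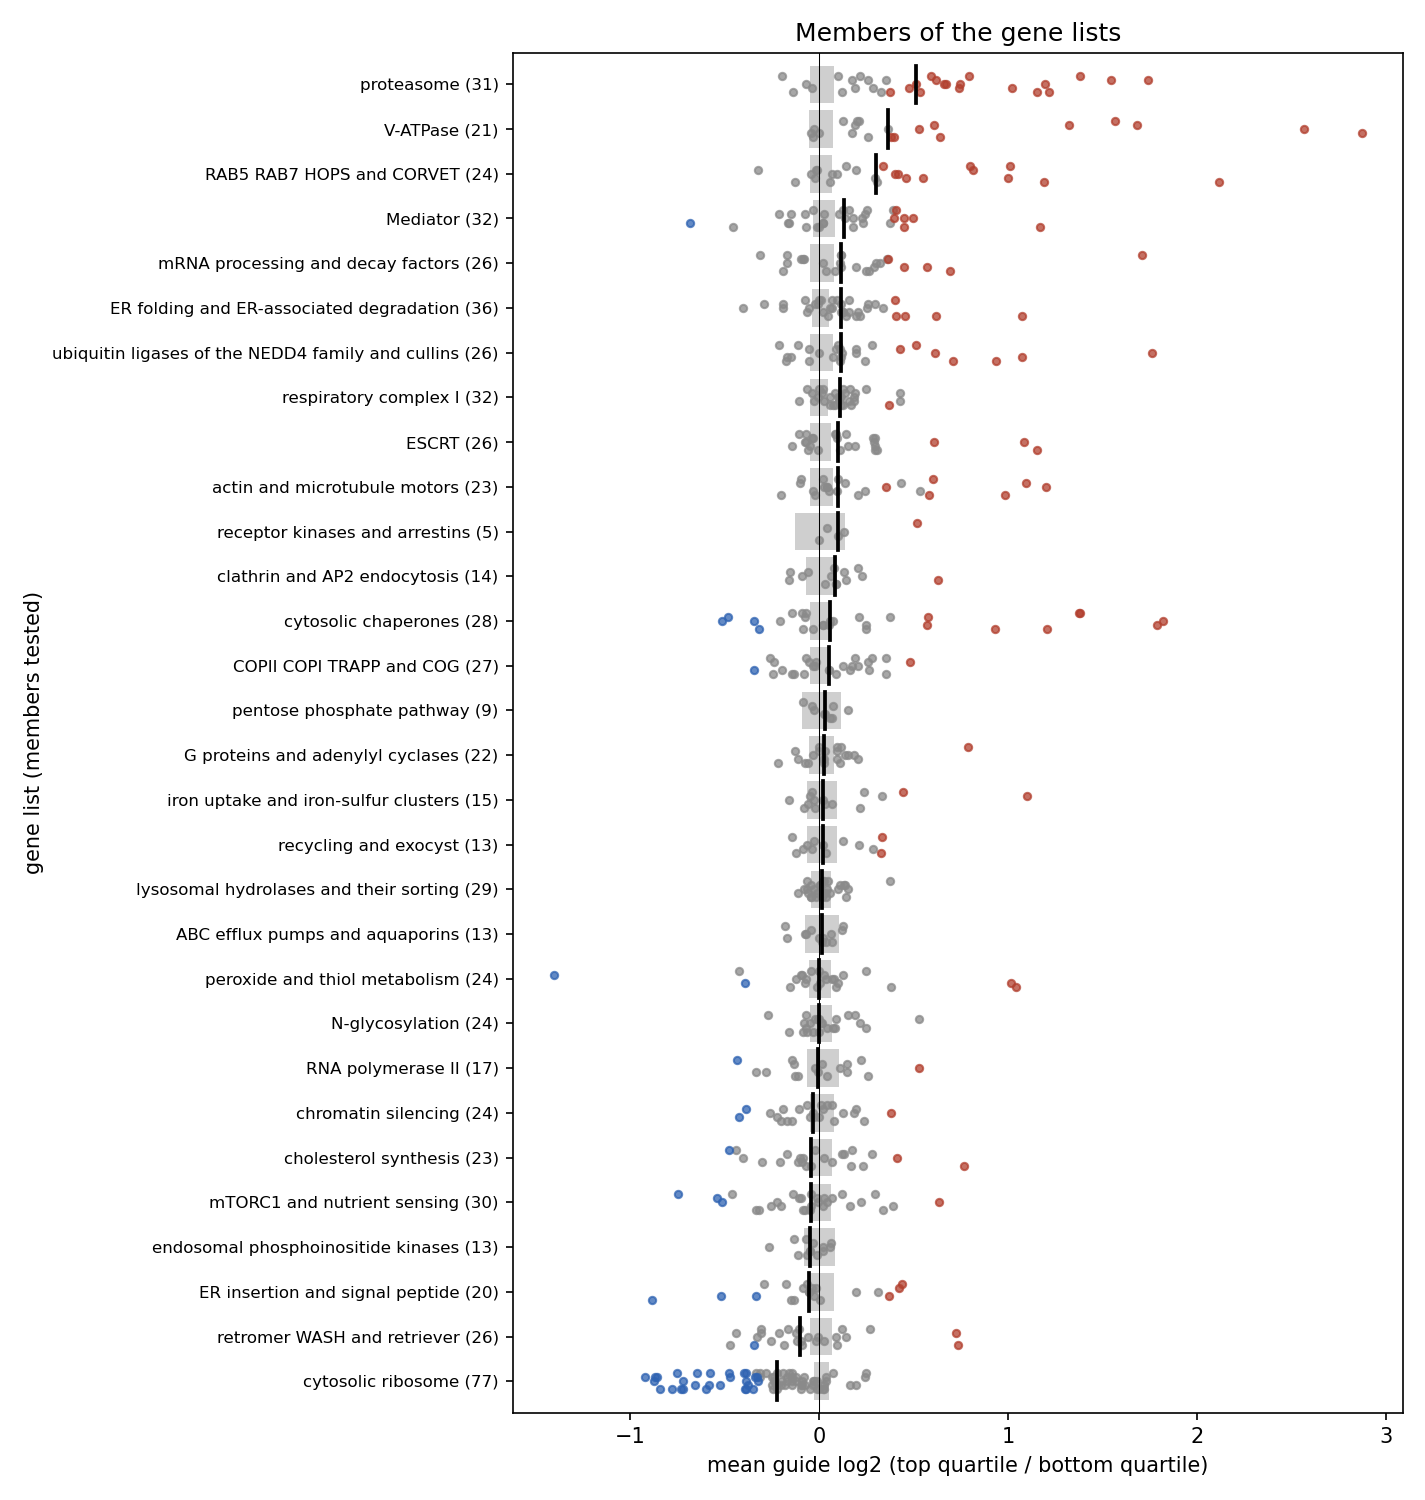
Each point is 1 member of a gene list, placed by its mean guide log2 ratio of top to bottom quartile; red and blue points passed the threshold toward the top and bottom, grey points did not, black bars are list medians and grey boxes the middle 95% of medians of 10000 matched random lists. Proteasome and V-ATPase medians of 0.51 and 0.36 lie above their boxes, and the ribosome median of -0.22 below its own.

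Genes with 2 separately targeted starts gave an internal comparison across guide sets. Of 60 genes called at the first start, 34 had the same sign at the second, or 56.7% (95% exact interval 43.2% to 69.4%), and 6 were called there, 4 of them in the same direction, SLC1A5 among these. Their median size was 0.52 at the first and 0.07 at the second start. Over all 1227 such genes the share was 52.6% (49.7% to 55.4%), with a correlation across genes, which are not independent replicates, of 0.12 (Pearson) and 0.03 (Spearman).

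Guides against essential genes were less abundant than non-targeting guides on the day of the sort. Over the counts of both libraries, the median log2 abundance relative to non-targeting guides was -0.48 for the proteasome and -0.38 for the cytosolic ribosome, both at percentile 0 of random lists, and -0.46 for RNA polymerase II, at percentile 0.150. For the receptor kinases and arrestins it was -0.15, at percentile 58.2. No member of these 4 lists was called below the non-targeting guides by itself, where the SD between non-targeting guides ran from 0.686 in H3 to 1.53 in H7. No starting pool was used here, so these values combine losses during growth with the make-up of the pool.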

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

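The H4 bottom library, which no comparison used, was read for guide abundance as planned, with 1 target singled out after the values were seen. Among 2410 targets of that library, NUP93, a nucleoporin, was the 1 whose guides lay below the non-targeting guides past the threshold. Its mean log2 abundance was -2.13 ± 0.29 (SD, n = 5 guides), a 4.38-fold lower count, with a permutation adjusted p of 0.0411. Without a usable top library or a starting pool, no explanation was tested.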

How the results depend on the processing

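Leaving out guides listed in 1 library, guides listed under more than 1 target or sublibrary H7, another seed, abundance from single libraries, TMM scaling for the lists and every setting for genes with 2 starts were chosen after seeing the data. Top and bottom were compared within each sublibrary, but repeated sorts could not be paired because each group held 1 library. Under all 16 alternatives 0 called targets were called in the opposite direction, and 47 of 106 named calls passed in each. With edgeR, 243 targets passed (146 top, 97 bottom), with 30 in H1, 68 in H2, 85 in H3, 48 in H5, 4 in H6 and 8 in H7; 234 of them were shared with the main test. With the farthest guide left out, 310 passed (202 top, 108 bottom), with 27 in H1, 97 in H2, 119 in H3, 62 in H5, 3 in H6 and 2 in H7; 308 were shared, and tests then rest on 1 guide fewer. The rank-sum test gave 282 top calls, with 118 in H2, 144 in H3 and 19 in H6. With no filter, H6 had 2 calls and H7 had 4. The mean of the 3 farthest guides gave 19 in H6 and 12 in H7, the median of the guides 11 in H7, and adjustment within each sublibrary 5 in H6 and 8 in H7. The cause was not tested. All other counts stayed within 1.5 times of the main count; over all sublibraries the remaining settings gave 482 to 749 calls. Of the 106 named calls, 51 were lost with edgeR, 40 without the farthest guide, 30 by rank sum, 19 by the median, 14 with the 3 farthest guides, 8 with no filter and 6 when adjusted within sublibraries. List medians outside the random range kept their sign in each of 4 settings; 10 of 32 moved with the 3 farthest guides and 1 with every start counted. Median abundance moved to -0.26 (ribosome) and -0.68 (proteasome) in the bottom library alone, and to -0.53 and -0.32 in the top library alone, as their top-to-bottom ratios imply. In each compared sublibrary the SD expected from counting reads was below the SD of the non-targeting guides. Reads do not give the number of cells or templates per guide, so a limit from these stays open.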

Other observations

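The gene lists in this part, and the test on the ribosome list, were chosen only after the calls had been seen, so their percentiles describe these libraries and are not independent evidence. DNA replication genes stood on the bright side: of 53 compared members 24 were higher in the top library and 3 in the bottom, and the median log2 ratio was 0.26. The polymerase delta subunits POLD2 and POLD1 had 2.11 ± 0.38 and 1.42 ± 0.83, the primase subunits PRIM1 and PRIM2 1.95 ± 0.14 and 1.45 ± 0.64, the clamp loader RFC4 1.83 ± 0.11 and the single-strand binding protein RPA2 1.71 ± 0.46. The helicase subunits MCM4, MCM5 and MCM6 went the other way at -0.35, -0.37 and -0.44, and MCM2, MCM3 and MCM7 of the same helicase had 0.06, -0.09 and 0.06 and did not pass (n = 5 guides in each).

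Factors of the small subunit processome, which assembles the small ribosomal subunit, stood on the dim side. Of 38 compared members 24 were higher in the bottom library and 0 in the top, and the median was -0.67 at percentile 0 of matched lists. DDX10 had -1.05 ± 0.41, PDCD11 -0.97 ± 0.50, RCL1 -0.98 ± 0.20 and the methyltransferase FBL -0.93 ± 0.46. Of 17 pre-mRNA 3' end processing genes 6 were higher in the bottom library, FIP1L1 and SYMPK among them, and NUDT21 was higher in the top at 1.11 ± 0.60; the median was -0.23 at percentile 0. Of 10 genes of the m6A writer and its nuclear reader 3 were higher in the bottom library, CBLL1, YTHDC1 and ZC3H13 (-0.50 ± 0.30). The other 7 did not pass, METTL3, METTL14 and WTAP of the writer among them at 0.02, -0.08 and 0.12. The median of the list was -0.09 at percentile 1.05. The list of nuclear pore genes and partners had 34 members, of which 17 are in H4 and 16 were compared. Of these 16, 5 were higher in the top library, such as NUP62 at 1.47 ± 0.38. RCC1, which is not a nucleoporin, was higher in the bottom at -0.41. The median was 0.14 at percentile 99.9. Translation initiation factors of eIF2B and eIF3 went both ways. Of 18 such genes 5 were higher in the top library, EIF2B5, EIF2B4 and EIF2B3 at 1.36 ± 0.33, 1.01 ± 0.81 and 0.99 ± 0.30 and also EIF3D and EIF3E at 1.07 ± 0.71 and 0.50 ± 0.39. In the bottom 3 were higher, EIF3I, EIF3G and EIF3A at -0.87 ± 0.42, -0.81 ± 0.20 and -0.62 ± 0.51. The median of the 18 was -0.08 at percentile 0.830.

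Low guide counts of essential genes could pull the DNA replication list away from 0. The median lay at percentile 100 of lists matched on sublibrary and guide count, but the list was chosen after its members had been seen among the calls, so this percentile does not decide. A split added later took the 10 members with at least the median guide count of their sublibrary. They had a median of 0.077 (95% exact interval -0.08 to 0.65), and the other 43 had 0.51. The counts were read after growth under the guides, so effective repression can itself lower them. The split therefore does not decide, and low counts stay open. Other essential groups differed in direction, with list medians of -0.22 for the ribosome, -0.003 for RNA polymerase II and 0.51 for the proteasome. The ribosome list argues only against every loss of fitness raising the ratio, and a part for fitness stays open. A candidate explanation is that cells held before division are larger and carry more receptor; the mitosis and cytokinesis list, with 9 of 47 members higher in the top and 2 in the bottom and a median of 0.15, lay at percentile 100, but it too was chosen after the calls had been seen, so it does not decide. Cell size was not measured here, and MCM4, MCM5 and MCM6 above went against the direction it gives, while MCM2, MCM3 and MCM7 lay near 0.

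Single guides that vanish from one library may set a gene's mean. In C2orf54, ZMYM5 and LSM6, 1 guide had 1598, 806 and 179 counts in the top library and 0 in the bottom, at least 519-fold, 205-fold and 47.9-fold higher against a floor of 3 counts per library. The other 4 guides of LSM6 had a mean of 1.22 ± 0.19, so the absent guide was not the only source of its call. For C2orf54 and ZMYM5 the other 4 had 0.41 ± 0.79 and 0.58 ± 0.93, and a real effect cannot be told apart from chance loss of 1 guide, since these means lie within their spread of 0. No biological explanation was tested.

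The wider spread of non-targeting guides in H7 is a candidate explanation for its fewer calls, 0.557% of targets against 7.34% in H3. When H3 targets were set against the non-targeting guides of H7, 3.22% were called, above the share in H7, so the spread was not the whole cause. Set against the non-targeting guides of H3, 4.05% of H7 targets were called, still below H3, and how much of the gap belongs to the spread stays open. The genes that each sublibrary holds differ, and that was not tested.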
